A study of Rattus norvegicus with 12 samples.

How the data were processed

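Lysates of whole embryonic rat brain (E17-E18, per the labels' protocols) were immunoprecipitated with a rabbit antibody against Staufen2 (6 samples) or with preimmune antibody (6 samples). The RNA that came down was amplified, biotin-labelled and hybridised to Illumina rat BeadChip arrays. One tissue label reads P18 in place of the E17-E18 of the protocols. The submitters' processing notes name RMA; its version and the array annotation are not given in the sources used here. The labels speak of repeated experiments without saying which brains or lysates each array came from, so the p-values measure the spread between these arrays, part of which may be technical.

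The authors deposited a table of 22226 probes with, per array, a raw signal intensity and a detection p-value. Signal columns are named by sample. Detection p-value columns are headed by codes that the labels do not hold, so each was taken to belong to the signal column beside it in the file, and this was checked against the signals. Sorted by signal, each array's own column was out of order for 205 to 268 of 22225 neighbouring pairs of probes, against at least 6744 for any other array's column. The 12 columns of bead standard errors were not used. The deposited value table holds log2 values, which were found equal to the log2 of the raw signal for all 22226 probes of every array within a tolerance of 0.0001, so no background correction or scaling between arrays is visible in it. Probe symbols were updated through a reference gene table of assembly GRCr8, used for names only. By current symbol 8086 probes matched, by gene number 5355 and by 1 older symbol 3402. Another 69 matched several older symbols and 5117 matched none, and both kinds kept the symbol of the file. The remaining 197 had no symbol.

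Signals were background-corrected with limma's normexp model, with the background inferred from the detection p-values and an offset of 16, and quantile normalized. Probes with a detection p-value under 0.05 on at least 6 of the 12 arrays were tested, which left 9136 probes. Depth on an array is its signal over background, and the share of detected probes ran from 11.6% to 48.8%. The groups were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over the tested probes, threshold 0.05). Differences are Staufen2 minus preimmune and are given with the standard error of the fit (SE). Gene lists were tested with limma's camera at a preset correlation of 0.01, on 1 probe per gene, the one with the highest mean, which gave 9025 genes. Lists with at least 5 measured members were tested, 25 in all, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry, which tests each list without comparing it with other genes, were run beside it (fry called 13 lists). The shift of a list is the mean log2 difference of its members minus that of the other genes. The share of detected probes was compared with a two-sided exact permutation test over all splits of the 12 arrays. A probe detected on no array of a group has only a bound there: the fold is given as at least the bright group's mean against the mean, per array of the dim group, of the higher of the lowest normalized value among detected probes and the probe's own value.

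The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 10 with the highest and the 8 with the lowest log2 difference among genes past the threshold whose groups of arrays did not overlap and which had an official symbol, every measured member of a short list of Staufen and dendritic candidates, and up to 3 members with the smallest adjusted p of each list past the threshold. Some single-gene results are not reported here.

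The pipeline was tested on simulated data with 50 probes at each of 4 known changes. At equal RNA yields in all arrays, all simulated changes of 1 or 2 log2 units were called, and 12 of 10358 unchanged probes were called. Yields were estimated per array from the brightest probes of the Staufen2 mean, as the median share of that mean left after subtracting the array's lower quartile of signal. At these yields, where the lowest Staufen2 array was 8.39 times the highest preimmune array, and with 1 RNA composition in both groups, 2849 of 9689 unchanged probes were called higher and 1105 lower. Calls of changed probes then reached 88% and 96% for increases of 1 and 2 log2 units, and 24% and 38.8% for decreases of 1 and 2. A further simulation, added after seeing the data, used the median signal over background of bright probes as the yield, with a ratio of 6.14. There 2403 of 9669 unchanged probes were called higher and 896 lower.

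A second analysis was chosen after seeing the data, once the simulation had shown these calls. It was run with 1 set of cut-offs, and others were not tried. It took the 1951 probes whose signal over background averaged at least 500 over the 12 arrays, subtracted as background the median signal of probes with detection p-values between 0.4 and 0.6, and floored the result at 10. Values were then put on the log2 scale and each array was centred on its median. The test used the 10 arrays with at least 20% of probes detected, which leaves out preimmune replicates 2 and 6. In the simulation at the first yields it called 6 of 1841 unchanged probes higher and 12 lower, and at the second yields 7 and 3 of 1859. Each simulated yield was 1 factor per array, with the same noise on every array. Median centring removes such a factor, so these low counts do not cover unequal amplification. At the first yields 10 simulated arrays had at least 20% of probes detected, and at the second 11, so the second differs from the data there. Values from it are named as bright-probe values.

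Alternatives covered the deposited log2 values, median centring, 2 other background corrections, 2 other detection filters, each array left out, the label numbers as a block, array weights, stricter thresholds, an estimated correlation and the mean of a gene's probes. Those added after seeing the data were the bright-probe values, the run of codes heading the detection columns (a first run of 8 arrays and a second of 4, whose meaning the labels do not give), the averaging of the closest pairs of arrays and the removal of preimmune replicates 2 and 6.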

Results

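RNA recovered with Staufen2, a double-stranded RNA-binding protein of neuronal ribonucleoprotein particles, was compared with RNA recovered with preimmune antibody from embryonic rat brain, to find which transcripts the particles hold. Each group had 6 arrays. The Staufen2 array labelled without a number is called replicate 0 here, and the others are replicates 1 to 5. The preimmune arrays are replicates 1 to 6.

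More RNA was measured after Staufen2 than after preimmune immunoprecipitation. The share of probes detected was 47.4% ± 1.25 (SD, n = 6) in Staufen2 immunoprecipitates and 25.4% ± 9.32 (SD, n = 6) in preimmune ones. The difference of 22.0 percentage points came with no overlap between the groups (exact permutation test, two-sided, p = 0.00216, the smallest that 6 against 6 arrays allow). Mean raw signal per probe was 452 ± 63.7 (SD, n = 6) against 97.9 ± 22.7 (SD, n = 6), with the same exact p of 0.00216. Among the preimmune arrays the detected share was 11.6% for replicate 6, 17.6% for replicate 2, 24.8% for replicate 5 and between 29.8% and 34.8% for replicates 1, 3 and 4. The Staufen2 arrays lay between 45.4% and 48.8%. The median signal over background of bright probes on a preimmune array was between 0.418% and 11.2% of the Staufen2 mean. In the first run of codes heading the file's columns, with 4 arrays per group, the detected shares were 47.6% and 29.0%. In the second run, with 2 arrays per group, they were 47.1% and 18.2%. The number of arrays limits the precision of these values.

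**Figure D1:**
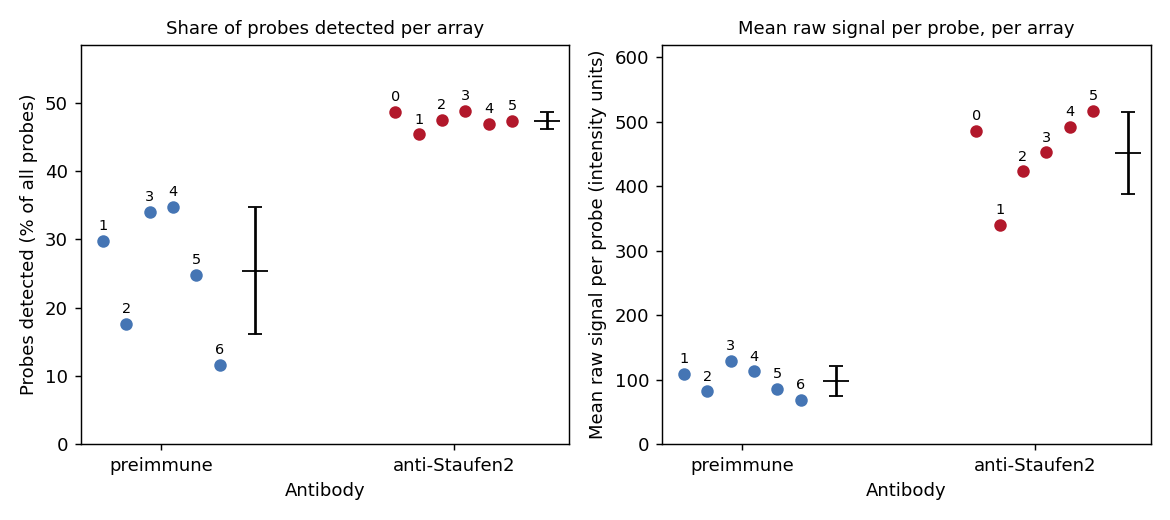
Share of probes detected (percent of all probes, left) and mean raw signal per probe (intensity units, right) on each array, by antibody. Points are arrays labelled by replicate and black bars are the mean and SD of each group; every Staufen2 array lies above every preimmune array, with detected shares of 45.4% to 48.8% against 11.6% to 34.8%.

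Transcripts of Atg12, a ubiquitin-like protein of autophagy, Borcs7, a subunit of a lysosome-positioning complex, and Rbm8a, a core protein of the exon junction complex, had the largest differences in favour of Staufen2 immunoprecipitates, relative to the rest of the array, among genes whose groups of arrays did not overlap. Atg12 was higher by a log2 difference of 4.68 ± 0.42 (SE, n = 6 per group; adjusted p = 5.0e-06), with a raw signal of 10105 ± 2021 (SD) against 117 ± 42.5. Borcs7 and Rbm8a were higher by 4.45 ± 0.37 and 4.37 ± 0.47. Gosr2, a Golgi SNARE, Urm1, a ubiquitin-like modifier, and Atp6v0e2, a proton pump subunit, followed at 4.32, 4.29 and 4.29. Rgs4, a regulator of G protein signalling, Ppp1r11, a phosphatase inhibitor, Arpin, an inhibitor of actin branching, and Ggps1, an enzyme of isoprenoid synthesis, were at 4.02, 3.98, 3.86 and 3.83. On bright-probe values these 10 genes were higher by 2.83 for Arpin to 3.55 for Atg12, in another order, with Urm1 at 3.53 above Rbm8a at 3.25. All were detected on the 6 Staufen2 arrays. Of the 6 preimmune arrays 5 detected Rbm8a and Urm1, 4 detected Atg12, Borcs7 and Arpin, 3 detected Gosr2, Atp6v0e2, Rgs4 and Ppp1r11, and 2 detected Ggps1, so the sizes and their order rest partly on preimmune values at background.

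At the low end, the ribosomal protein transcripts Rps29 and Rpl36 were lower relative to the rest of the array by -3.05 ± 0.27 (SE, n = 6 per group; adjusted p = 4.4e-06) and -2.96 ± 0.28 (adjusted p = 7.8e-06), but at 1.21 and 1.38 without scaling. With median centring the Rpl36 call ended (-0.97, adjusted p = 0.0832). Their bright-probe differences were -3.23 and -3.02. Ndufab1, an acyl carrier protein of the respiratory chain, had -4.05 ± 0.25 (adjusted p = 9.7e-07) after normalization, with raw signals of 181 ± 61.5 (SD) and 216 ± 107 and a difference of -0.14 without scaling. Rbm25, Exo5, Fsd1, Nebl and Kcnj4 completed the 8 lowest genes, with mean raw signals of at most 324 and no bright-probe value. Nebl and Kcnj4 were at -2.87 and -2.85 after normalization but at 0.15 and 0.12 without scaling, and the raw signal of Nebl was 127 ± 6.61 (SD) against 115 ± 8.04. The normalized preimmune values of Nebl were 7.39 to 8.17 on replicates 1, 3 and 4 but 10.4 and 11.9 on replicates 2 and 6. A second probe of Rbm25 had a difference of 0.02 (adjusted p = 0.888) where the first had -3.04.

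Over all 9136 tested probes 2860 were higher and 1321 lower in Staufen2 immunoprecipitates, of which 1359 and 982 differed at least 2-fold (limma, adjusted p under 0.05). The same procedure applied to simulated arrays of 1 RNA composition at estimated yields called 2849 of 9689 unchanged probes higher and 1105 lower. At a second estimate of the yields, simulated after seeing the data, it called 2403 of 9669 higher and 896 lower, so these counts do not measure how many transcripts differ in share. On the 1951 bright probes, an analysis chosen after seeing the data, 723 were higher and 594 lower, and the simulations called 6 and 12 of 1841 unchanged probes at the first yields and 7 and 3 of 1859 at the second. Of these bright calls 706 and 358 were made in the same direction over all tested probes, and 1 in the opposite direction.

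Every decrease is relative to the rest of the array. Mean raw signal was higher in Staufen2 immunoprecipitates for 9133 of the tested probes. Without scaling, limma called 8904 probes higher and 0 lower, 8908 probes were at an unadjusted p under 0.05, and the median log2 difference was 1.64, against 0.08 after quantile normalization. The split moved to 3122 higher and 3784 lower with median centring, to 264 and 970 over the 1683 probes detected on all 12 arrays, to 3290 and 2887 with array weights, and to 2812 and 2362 without preimmune replicates 2 and 6. With the code run as a block 3057 were higher and 1439 lower. The first run alone gave 2797 and 1477. The second run alone, with 2 arrays per group, gave 0 calls with limma and 3041 probes at an unadjusted p under 0.05.

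**Figure D2:**
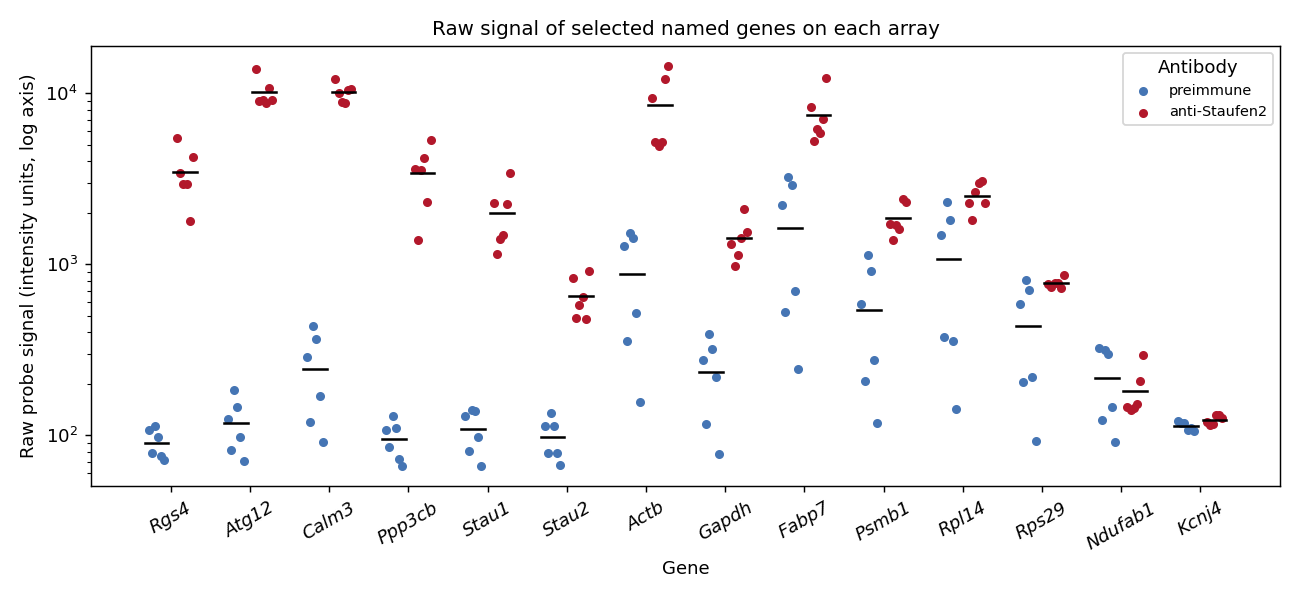
Raw probe signal (intensity units, log axis) of 14 named genes on each array, in blue for preimmune and red for Staufen2 immunoprecipitates, with black lines at the group means. Rgs4 and Atg12 are near background in preimmune immunoprecipitates (means 90.6 and 117) and at 3456 and 10105 in Staufen2 ones, while the groups overlap for Ndufab1 (216 and 181).

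Among the candidates fixed beforehand, Rgs4, Calm3, which encodes calmodulin, Stau1, the paralog of Staufen2, and Map1b, a microtubule-associated protein, were higher in Staufen2 immunoprecipitates over all tested probes and on bright-probe values. Rgs4 differed by 4.02 ± 0.33 on the log2 scale (SE, n = 6 per group; adjusted p = 2.8e-06) and Calm3 by 1.81 ± 0.14 (adjusted p = 2.3e-06). Their bright-probe differences were 3.21 ± 0.30 and 1.63 ± 0.17. Stau1 differed by 2.36 ± 0.44 (adjusted p = 0.000854) and Map1b by 2.43 ± 0.65 (adjusted p = 0.00794), and by 1.26 and 1.12 on bright-probe values. The Stau2 transcript itself was higher by 1.22 ± 0.38 (adjusted p = 0.0182), a call that ended within the first code run (0.94, adjusted p = 0.0575). Map2, the dendritic microtubule-associated protein, was higher by 1.35 ± 0.45 (adjusted p = 0.0238). The Map2 call ended without Staufen2 replicate 0 (1.09, adjusted p = 0.0579), without replicate 2 (1.27, adjusted p = 0.0517) and with the closest pairs of arrays averaged (1.31, adjusted p = 0.0669). Stau1, Map1b and Map2 were detected on 4 of the 6 preimmune arrays and Rgs4 and Stau2 on 3. Stau2 and Map2 lay outside the bright set and so had no bright-probe value. Outside that set the simulation at the first yields called 2840 of 7848 unchanged probes higher, so yield alone may give the Stau2 and Map2 calls.

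Gapdh, a glycolytic enzyme, and Actb, cytoplasmic actin, were relatively lower by -0.97 ± 0.29 (SE; adjusted p = 0.0144) and -0.65 ± 0.23 (adjusted p = 0.0296), with bright-probe differences of -1.34 and -0.98, but stood at 0.79 and 1.14 with median centring and at 2.77 and 3.56 without scaling. The Actb call ended without preimmune replicate 1 or 2 or Staufen2 replicate 1, 2 or 3, with differences between -0.62 and -0.53. It also ended without preimmune replicates 2 and 6 (-0.56, adjusted p = 0.0830) and with the closest pairs averaged (-0.57, adjusted p = 0.0672), and its difference was -0.046 in the second code run. Arc, an activity-regulated dendritic transcript, had -2.19 ± 0.59 (adjusted p = 0.00874) after normalization but 0.41 without scaling, with raw signals of 138 ± 9.52 (SD) and 104 ± 5.33. Its normalized preimmune values were 6.88 to 7.43 on replicates 1, 3 and 4 but 9.58 and 10.9 on replicates 2 and 6. Within the first code run its call ended (-1.45, adjusted p = 0.0524). Bdnf was detected on all 6 Staufen2 and 0 preimmune arrays, at raw signals of 137 and 71.2 (difference 0.21, adjusted p = 0.000501, and lower by -0.43 with median centring, adjusted p = 4.7e-05), too near the detection limit for a bound on its fold. Fmr1, detected on 4 preimmune arrays, and Hprt1 did not pass the test, at 0.40 ± 0.24 (adjusted p = 0.185) and 0.43 ± 0.24 (adjusted p = 0.168), but stood at 1.89 and 3.43 without scaling (adjusted p = 4.5e-08 and 1.4e-09), and Hprt1 at 1.91 with median centring (adjusted p = 1.2e-05). Camk2a and Bcl2l1 were not tested, being detected on 5 and 1 of the 12 arrays.

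Transcripts of ribosomal proteins and of oxidative phosphorylation were lower relative to other transcripts in Staufen2 immunoprecipitates, over all tested probes and on bright-probe values. Of 70 cytosolic ribosomal protein genes 48 were lower, 3 higher and 19 not called, and adjusted over the list alone 50 were lower and 4 higher. Their shift was -1.23 (camera, adjusted p = 3.1e-19; adjusted p = 0.377 with an estimated correlation), -0.0064 with median centring and 0.65 without scaling. With median centring the median and the test pointed up without a call (adjusted p = 0.235). Without scaling the mean and median lay above other genes while the test pointed down (adjusted p = 4.8e-07). On bright-probe values 46 of 53 were lower at a shift of -1.81 (adjusted p = 2.3e-13; adjusted p = 0.417 with an estimated correlation). Rpl14 and Rps18 were lower by -2.41 ± 0.19 and -2.13 ± 0.19 (SE), calls that ended with median centring (-0.63 and -0.37, adjusted p = 0.307 and 0.551). The higher members included, named after its value was seen, Rpl15 at 2.77, which 4 of the 6 preimmune arrays detected. Of 56 oxidative phosphorylation genes 37 were lower and 6 higher, and 38 and 6 adjusted over the list alone. Their shift was -1.14 (camera, adjusted p = 9.4e-13; adjusted p = 0.377 with an estimated correlation) and -1.22 on bright-probe values (adjusted p = 1.7e-05; adjusted p = 0.417 with an estimated correlation), but 0.16 with median centring (adjusted p = 0.0747) and 0.62 without scaling, where the mean and median lay above other genes and the test pointed down (adjusted p = 0.0210). The ATP synthase subunits Atp5pf and Atp5po were at -1.99 ± 0.18 and -1.79 ± 0.16, and at 0.049 and 0.067 with median centring.

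The proteasome, chaperone and neural progenitor lists were also called relatively lower at the preset correlation, the last with few of its genes called. Of 34 proteasome genes 18 were lower and 3 higher, the same counts as adjusted over the list alone. Their shift was -0.88 (camera, adjusted p = 2.7e-06; adjusted p = 0.377 with an estimated correlation) and -1.33 on bright-probe values (adjusted p = 5.6e-05; adjusted p = 0.417 with an estimated correlation), but 0.28 with median centring (adjusted p = 0.0650) and 0.66 without scaling (adjusted p = 0.558), and the call ended over probes detected on all 12 arrays (-0.28, adjusted p = 0.0720). The core subunits Psmb1, Psmb2 and Psmb5 were at -2.15, -2.20 and -1.79, and with median centring at -0.15, -0.16 and 0.11 without a call. Of 37 chaperone genes 11 were lower and 3 higher, and 10 and 3 adjusted over the list alone. Their shift was -0.61 (camera, adjusted p = 0.00113; adjusted p = 0.706 with an estimated correlation) and -1.18 on bright-probe values (adjusted p = 0.000969; adjusted p = 0.417 with an estimated correlation), but 0.20 with median centring (adjusted p = 0.235), 0.45 without scaling (adjusted p = 0.278) and 0.17 over probes detected on all 12 arrays (adjusted p = 0.675). The cyclophilin Ppia and the chaperonin subunits Tcp1 and Cct4 were at -1.55, -1.44 and -1.49, and with median centring at -0.13, 0.45 and 0.36 without a call. Of 21 neural progenitor markers Dbi, Fabp7, Vim and, named after its value was seen, Mki67 were lower, at -2.32, -1.40, -1.69 and -0.36, and 0 were higher. The remaining 17 were not called, and over all genes tested 1276 of 9025 were called lower. Adjusted over the list alone 4 were lower. Mki67 was detected on 2 of the 6 preimmune arrays, and with median centring Dbi, Fabp7 and Vim were at -0.42, 0.18 and 0.19 without a call. The shift was -0.45 (camera, adjusted p = 0.0298; adjusted p = 0.836 with an estimated correlation) and -1.44 over 6 genes on bright-probe values (adjusted p = 0.0443; adjusted p = 0.417 with an estimated correlation). This call ended with median centring (-0.28, adjusted p = 0.505), without scaling (-0.20, adjusted p = 0.0774), without preimmune replicate 4 (-0.42, adjusted p = 0.0545) or 5 (-0.34, adjusted p = 0.0818), with the closest pairs averaged (-0.40, adjusted p = 0.0573), without a detection filter (-0.34, adjusted p = 0.108) and within the second code run (-0.30, adjusted p = 0.206).

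Red blood cell markers had the lowest shift, -1.49 over 10 genes (camera, adjusted p = 0.00456; adjusted p = 0.377 with an estimated correlation), with 5 lower and 0 higher, the same counts as adjusted over the list alone. Kel, Epb42 and Slc4a1, at -2.38, -2.33 and -2.38, had raw signals of 122 to 140 against 106 and stood at 0.20, 0.37 and 0.40 without scaling. The list had too few bright probes to test. Without scaling its shift was -0.52 (adjusted p = 8.7e-07). Its call ended with median centring (-0.81, adjusted p = 0.264), without a detection filter (-0.67, adjusted p = 0.108) and over probes detected on all 12 arrays (-1.07, adjusted p = 0.506), and that of Slc4a1 ended within the first code run (-1.55, adjusted p = 0.0576).

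Protein kinases and phosphatases and the small GTPase cycle were higher relative to other transcripts in Staufen2 immunoprecipitates. Of 82 kinase and phosphatase genes 41 were higher and 4 lower, and 42 and 4 adjusted over the list alone. Their shift was 0.64 (camera, adjusted p = 0.00456; adjusted p = 0.836 with an estimated correlation). Prkacb, a catalytic subunit of protein kinase A, was higher by 1.02 ± 0.10 (SE), and Ppp3cb, a catalytic subunit of calcineurin, by 3.71 ± 0.37, with 4 of the 6 preimmune arrays detecting it. Csnk2a2, a catalytic subunit of casein kinase, had a fitted difference of 3.17 ± 0.25 but was detected on 1 preimmune array, at a mean raw signal of 74.5 where the backgrounds were 66.6 to 79.6, so that this size is not a measured fold. On bright-probe values 19 of 35 were higher and 6 lower, at a shift of 0.60 that missed the threshold (adjusted p = 0.0664). Of 85 genes of the small GTPase cycle 39 were higher and 5 lower, and 40 and 5 adjusted over the list alone. Their shift was 0.66 (camera, adjusted p = 0.00722; adjusted p = 0.836 with an estimated correlation). On bright-probe values 23 of 40 were higher and 7 lower (shift 0.63, adjusted p = 0.0443; adjusted p = 0.417 with an estimated correlation). The 3 members with the smallest adjusted p, Rgs4, Rgs2 at 2.12 ± 0.20 and Rgs8, encode regulators that act on heterotrimeric G proteins and not on small GTPases. Rgs8 was detected on 0 preimmune arrays and was at least 3.01-fold higher (adjusted p = 9.6e-06). Among small GTPases proper, named after their values were seen, Rab5b, Rhoa and Cdc42 were higher by 3.30, 2.26 and 1.01, and Ran was lower by -1.80. Rab5b was detected on 4 of the 6 preimmune arrays.

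At the preset correlation all 8 of these list calls held with the code run as a block. Each run held as many Staufen2 as preimmune arrays, so the block could change the spread but not the shifts. With an estimated correlation, run without that block, 0 of the 8 passed (lowest adjusted p = 0.377). The list test was not run on simulated arrays of unequal yield, so what yield alone does to these lists was not measured. The shifts, by design the same with and without the block, were -1.23 for ribosomal proteins, -1.14 for oxidative phosphorylation, -0.88 for the proteasome, -0.61 for chaperones, -0.45 for neural progenitor markers, -1.49 for red blood cell markers, 0.64 for kinases and phosphatases and 0.66 for the small GTPase cycle. Within the first run these shifts were -1.37, -1.36, -0.97, -0.68, -0.51, -1.33, 0.56 and 0.56 in the same order. Within the second they were -0.98, -0.71, -0.62, -0.49, -0.30, -1.81, 0.82 and 0.88, and the neural progenitor call ended there (adjusted p = 0.206).

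**Figure D3:**
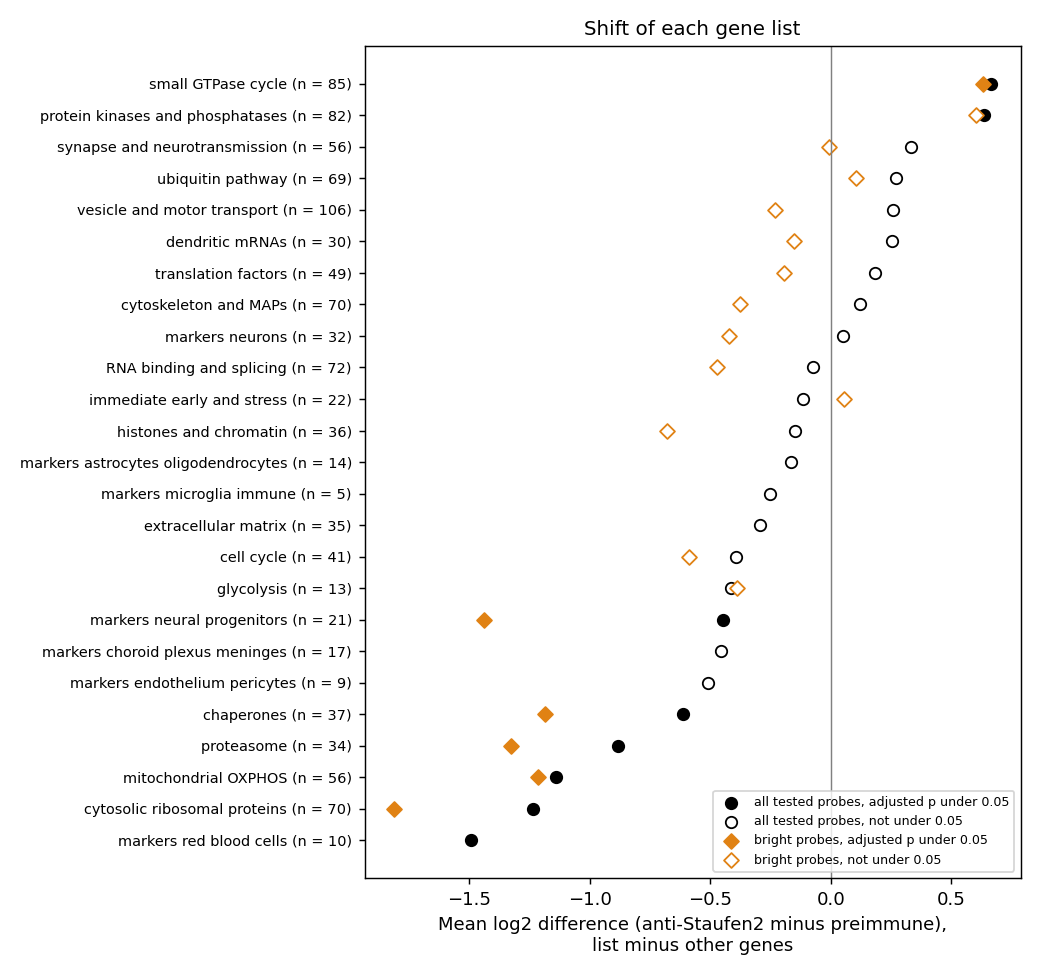
Shift of each of the 25 gene lists (mean log2 difference of its members minus that of other genes, Staufen2 minus preimmune) over all tested probes (black circles) and bright probes (orange diamonds), filled where the camera adjusted p with a preset correlation is under 0.05; n counts genes over all tested probes. Ribosomal protein, oxidative phosphorylation, proteasome, chaperone and neural progenitor lists lie left of 0 and the small GTPase cycle right of 0 with filled symbols in both, while with median centring the ribosomal protein, oxidative phosphorylation, proteasome and chaperone lists lay at -0.0064, 0.16, 0.28 and 0.20, and with an estimated correlation 0 lists were called, at adjusted p-values of at least 0.377 over all tested probes and 0.417 on bright probes.

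Camera called no neuronal or synaptic list over all tested probes. The list of synapse and neurotransmission genes had a shift of 0.33 (camera, adjusted p = 0.148), with 25 of 56 higher and 2 lower, and -0.0051 over 11 genes on bright-probe values. Vesicle and motor transport was at 0.26 (adjusted p = 0.496), dendritic mRNAs at 0.26 (adjusted p = 0.807) and the ubiquitin pathway at 0.27 (adjusted p = 0.491). Fry, which does not compare a list with other genes, called these 4 lists higher, at adjusted p-values of 0.00274 for synapse, 0.0230 for vesicle transport, 0.000176 for dendritic mRNAs and 0.00813 for the ubiquitin pathway. Fry also called immediate early and stress genes higher (adjusted p = 0.0122). In the simulations at unequal yields more unchanged probes were called higher than lower, so yield alone may give such fry calls. Neuron markers, cytoskeleton genes and translation factors had mean shifts of 0.053, 0.12 and 0.18 and medians above other genes, where the test pointed down, with adjusted p-values of 0.763, 0.763 and 0.852. RNA-binding and splicing genes had a shift of -0.073 (adjusted p = 0.464), histones and chromatin -0.15 (adjusted p = 0.225), the cell cycle -0.39 (adjusted p = 0.0998) and glycolysis -0.41 (adjusted p = 0.218). Immediate early and stress genes were at -0.12 (adjusted p = 0.852), with a median above that of other genes. Markers of astrocytes and oligodendrocytes had a shift of -0.16 (adjusted p = 0.824), where the median and the test pointed up. Markers of microglia were at -0.25 (adjusted p = 0.687), of endothelium and pericytes at -0.51 (adjusted p = 0.516), and of choroid plexus and meninges at -0.45 (adjusted p = 0.318). Extracellular matrix genes were at -0.29 (adjusted p = 0.0998).

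Camera did call some of these lists under alternatives. The list of synapse and neurotransmission genes was called within the first code run (0.44, adjusted p = 0.0235), with array weights (0.46, adjusted p = 0.00754), without Staufen2 replicate 4 (0.42, adjusted p = 0.0472) and without a detection filter (0.26, adjusted p = 0.00442). The cell cycle was called lower in the first run (-0.44, adjusted p = 0.0226), with array weights (-0.54, adjusted p = 0.0172), without preimmune replicate 2 (-0.48, adjusted p = 0.0488), without Staufen2 replicate 4 (-0.61, adjusted p = 0.00692) and without scaling (-0.14, adjusted p = 0.000449). Extracellular matrix genes were called lower with array weights (-0.33, adjusted p = 0.0212), without preimmune replicates 2 and 6 (-0.35, adjusted p = 0.0404) and without scaling (-0.63, adjusted p = 0.0261). Choroid plexus and meninges markers were called lower with array weights (-0.71, adjusted p = 0.0379) and without scaling (-0.28, adjusted p = 0.0117), and glycolysis with array weights (-0.70, adjusted p = 0.0383). Vesicle and motor transport was called higher with median centring (0.53, adjusted p = 0.000467), without scaling (0.63, adjusted p = 0.0261) and without a detection filter (0.29, adjusted p = 0.00152). The ubiquitin pathway was called higher with median centring (0.53, adjusted p = 0.0290) and without a detection filter (0.28, adjusted p = 0.00442). Median centring also gave calls for cytoskeleton genes (0.71, adjusted p = 0.00201), neuron markers (0.72, adjusted p = 0.0192) and translation factors (0.95, adjusted p = 0.000467).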

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

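Among 108 groups of 6 arrays examined, 9 held an array that stood apart from the other 5, where chance gives about 1 in 20 groups, or 5.4 of these. Values are normalized log2 values, and no explanation was tested for them. Preimmune replicate 5 was low for Atp5po at 11.7 (the others 12.5 to 12.6) and high for Ppia at 13.7 (13.4 to 13.5) and Tcp1 at 11.6 (10.4 to 10.7). Preimmune replicate 2 was high for Bcl2l1 at 6.73 (5.96 to 6.04). Staufen2 replicate 4 was low for Stau2 at 7.41 (8.06 to 8.44) and high for Vim at 10.5 (9.15 to 9.62). Staufen2 replicate 5 was low for Gosr2 at 10.3 (10.8 to 11.1) and high for Camk2a at 6.14 (6.04 to 6.07), and replicate 1 was high for Nebl at 6.23 (6.13 to 6.17).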

How the results depend on the processing

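The bright-probe, code-run, averaged-pair and left-out-pair alternatives were chosen after seeing the data; a block on the BeadChip was not run, since the columns used carry no barcode. Of 1301 comparisons over 50 named genes 1191 kept direction and side of the threshold, and of 706 over 25 lists 618 did. Many of these were fits without 1 array, which share the remaining arrays with the main fit and so change little by construction. Where the scaling changed, fewer were kept: 21 of 50 genes and 13 of 25 lists with the deposited values, and 32 and 11 with median centring. The count of 2860 probes higher moved to 8904 with the deposited values, 264 on probes detected on all 12 arrays, 801 with a 1.5-fold minimum, 723 on bright probes, 636 on these with the closest pairs averaged, and 0 in the second code run alone (limma; 3041 probes at an unadjusted p under 0.05). The count of 1321 lower moved to 0 with the deposited values (limma; 8908 at an unadjusted p under 0.05), 3784 with median centring, 2887 with array weights, 2362 without preimmune replicates 2 and 6, 757 at adjusted p under 0.01, 483 with a 1.5-fold minimum, 594 on bright probes, 529 on these with pairs averaged, and 0 in the second code run alone. Stricter thresholds and fewer probes or arrays lower some of these counts by construction; for the others the cause was not tested. Leaving out 1 array gave 2612 to 2948 higher, 1065 to 1817 lower, a detected-share difference of 19.2 to 23.9 percentage points, 5 to 7 lists lower and 2 to 3 higher. Lists called lower, 6 at first, were 0 with median centring, 2 on probes detected on all 12 arrays, 10 with array weights and 0 with an estimated correlation (camera; lowest adjusted p 0.377, while fry called 13 lists). Lists called higher by the direction of the test, 2 at first, were 7 with median centring, 5 without a detection filter, 1 on bright probes with or without averaged pairs, and 0 with an estimated correlation; the cause was not tested. With the deposited values the test called 3 lists higher and 6 lower, among the latter ribosomal proteins and oxidative phosphorylation, whose mean shifts there were above 0. The label numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.125 to 0.297, and 4 of 10 arrays correlated best with their own number. The labels state no pairing and no other pairing was fitted, so arrays paired in another way are not ruled out. With the replicate block 2595 probes were higher and 1519 lower, the neuron marker shift turned to -0.062, the extracellular matrix list was called lower (-0.36, adjusted p = 0.0413), and the calls of Actb (-0.65, adjusted p = 0.0572) and Stau2 (0.98, adjusted p = 0.0754) were not made. Signal over background limits what the preimmune arrays can show: 1156 tested probes were detected on none of them.

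With the deposited values nothing scales the arrays, and differences turned to 1.21 for Rps29, 1.05 Rbm25, 1.38 Rpl36, 0.80 Exo5, 1.12 Fsd1, 0.15 Nebl, 0.12 Kcnj4, 3.56 Actb, 0.41 Arc, 2.77 Gapdh, 2.40 Ppia, 2.54 Tcp1, 2.58 Cct4, 1.83 Rpl14, 2.08 Rps18, 1.98 Dbi, 2.69 Fabp7, 2.38 Vim, 0.20 Kel, 0.37 Epb42, 0.40 Slc4a1, 2.33 Atp5pf, 2.46 Atp5po, 2.19 Psmb1, 2.14 Psmb2 and 2.27 Psmb5. List shifts turned to 0.45 for chaperones, 0.65 ribosomal proteins, 0.72 glycolysis, 0.66 histones, 0.62 oxidative phosphorylation, 0.66 proteasome and 0.57 RNA binding. With median centring the genes that turned were Actb at 1.14, Bdnf -0.43, Gapdh 0.79, Tcp1 0.45, Cct4 0.36, Fabp7 0.18, Vim 0.19, Atp5pf 0.049, Atp5po 0.067 and Psmb5 0.11. Calls that ended there without turning were Rpl36 at -0.97, Rpl14 -0.63, Rps18 -0.37, Dbi -0.42, Ppia -0.13, Psmb1 -0.15 and Psmb2 -0.16 (adjusted p-values 0.0832 to 0.833). The lists that turned were chaperones at 0.20, glycolysis 0.47, histones 0.39, oxidative phosphorylation 0.16, proteasome 0.28 and RNA binding 0.42. On probes detected on all 12 arrays the shifts that turned were 0.17 for chaperones, 0.017 glycolysis, 0.54 histones and 0.52 RNA binding. On bright probes, and on these with pairs averaged, they were -0.38 and -0.36 for cytoskeleton, -0.15 and -0.14 dendritic mRNAs, 0.055 and 0.042 immediate early genes, -0.42 and -0.40 neuron markers, -0.0051 and -0.00071 synapse, -0.19 and -0.21 translation factors, and -0.23 and -0.22 vesicle transport. The small neuron marker shift also turned to -0.0091 with quantile normalization of uncorrected signals, -0.0091 with normexp at offset 50, -0.12 with array weights, -0.095 in the first code run, -0.0076 without preimmune replicates 2 and 6 and -0.032 without preimmune replicate 6. That of RNA binding turned to 0.013 without a detection filter, 0.081 in the second code run and 0.045 without preimmune replicate 5, and that of cytoskeleton to -0.026 with array weights.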

Other observations

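The gene families in the next sentences, and the tests of yield, of amplification and of near-identical arrays, were chosen after the values were seen. Transcripts of the calmodulin genes Calm3 and Calm2, which encode 1 protein sequence had different values, a difference that was not itself tested. Calm3 was higher in Staufen2 immunoprecipitates by 1.81 (bright-probe difference 1.63). Calm2 was relatively lower by -0.58 ± 0.10 (SE; adjusted p = 0.000635) and by -1.65 on bright-probe values, but stood at 0.52 with median centring (adjusted p = 0.376) and at 3.07 without scaling. Raw signals in preimmune and Staufen2 immunoprecipitates were 244 and 10160 for Calm3, and 2703 and 16247 for Calm2. Of the calcineurin catalytic subunits Ppp3cb was higher by 3.71 and Ppp3ca did not pass the test at -0.084 (adjusted p = 0.776), though it did with median centring (1.81, adjusted p = 0.00378); the difference between them was not tested. Of the beta tubulins Tubb2, Tubb2a, Tubb2b and Tubb3 were relatively lower by -1.44, -0.92, -1.53 and -0.99, but were not called with median centring (0.53, 0.62, 0.010 and 0.93) and stood at 2.53 to 3.13 without scaling. On bright-probe values they were lower by -1.72, -1.62, -2.23 and -1.30. Tubb5 and Tubb6, detected on 6 and 5 preimmune arrays, did not pass the test (-0.31, adjusted p = 0.458, and -0.65, adjusted p = 0.197), but Tubb5 was lower on bright-probe values (-0.82, adjusted p = 0.0150) and higher with median centring (1.30, adjusted p = 0.00733). The alpha globin Hba-a1 was among the brightest probes in preimmune immunoprecipitates, at a raw signal of 4941 against 12096, and was relatively lower by -1.11 (adjusted p = 0.0131) and by -2.54 on bright-probe values, but at 2.22 without scaling and not called with median centring (-0.30, adjusted p = 0.737). The globins Hbb and Hba-a3 did not pass the test over all tested probes (-1.11, adjusted p = 0.110, and -1.86, adjusted p = 0.0711). Hbb was lower on bright-probe values (-2.10, adjusted p = 0.0212), but at 0.066 with median centring (adjusted p = 0.951) and at 2.52 without scaling (adjusted p = 0.00820). Hba-a3, detected on 4 preimmune arrays, was lower with median centring (-1.10, adjusted p = 0.0293).

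On all tested probes a difference in RNA yield alone may account for many of the calls. Signals simulated from 1 composition gave 3915 calls among 7848 probes outside the bright set at one estimate of the yields and 3280 among 7810 at the other, where the data gave 2973 among 7194. On bright probes 1 composition is argued against: the highest correlation between a Staufen2 and a preimmune array was 0.581, below the lowest within Staufen2 (0.767) or within preimmune arrays (0.719, or 0.837 without replicates 2 and 6), across probes, which are not independent replicates. The real split of the arrays gave 4181 calls. The highest of 99 others drawn from the 462 splits gave 1, so that 1 of 100 was as large. The count thus follows the grouping by antibody. Every other split mixes arrays of high and low yield, so this comparison cannot tell a difference in composition from one in yield. Unequal amplification of small amounts of RNA cannot be told apart from binding by Staufen2, because the lowest Staufen2 yield on bright probes was 6.14 times the highest preimmune yield (8.39 times by the other estimate) and no arrays of like yield exist.

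Lower relative levels of ribosomal protein transcripts may reflect how Staufen2 particles are composed, what the preimmune immunoprecipitates hold, or the measurement. The samples held no input RNA, so a change in Staufen2 immunoprecipitates cannot be told from one in preimmune ones. Compression of bright signals on the Staufen2 arrays is argued against as the whole cause: 0% of 10000 lists matched on Staufen2 signal had a median as low as the -1.82 of 53 ribosomal protein genes on bright probes. The matched lists had a median of 0.38. They were not matched on how genes vary together, estimated at a correlation of 0.43 for ribosomal protein genes over all tested probes. The shares of 0% here and below are therefore not p-values. Gene span is argued against likewise, with 0% of 10000 lists matched on genomic span as low, at a median of -0.39; transcript length was not measured. Amplification from little RNA stays open, as above.

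The closest arrays of each group, Staufen2 replicates 2 and 3 and preimmune replicates 3 and 4, may each come from 1 preparation. The SD of their log2 ratios was 0.111 and 0.162, at most 0.488 times that of the next closest pair of the group. With each pair averaged to 1 sample, 2650 probes were higher and 1114 lower.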
